A study of Mus musculus with 2 samples.

How the data were processed

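H3K4me1 ChIP-seq was measured in activated Treg cells of 1 mouse biosample, as 2 technical libraries of the same biological replicate. The deposited file of each library holds whole-number read counts per region, not normalized, for 33643 regions numbered from 1 without gaps, with no header. The accompanying notes describe the counts as an enrichment quantification on the mm10 assembly, per the file headers of those notes, derived from the alignment of that library and from a further file common to both libraries. That further file was not analysed here. The aligner, the treatment of duplicate reads, the counting rule, the origin of the regions and their widths are not given in the sources used here. Duplicate handling would change the counts of the highest regions, and region width would change every count. No input control was used, so counts include background reads. The total over the regions, 384814 reads in library 1 and 369421 in library 2, is the part of each library that fell in the regions and not its sequencing depth.

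Libraries were grouped from their antibody label. With 1 group and 1 animal there was no comparison of conditions, so no model of differential enrichment was fitted and every p-value refers to these libraries or to the order of regions. The counts were read with Python 3.11.15 and NumPy 2.4.6 and tested with SciPy 1.17.1, and plots were drawn with Matplotlib 3.10.9. The deposited counts were used as they are, with no filter unless stated. A log2 scale used a pseudocount of 1. Agreement between libraries was measured by an exact two-sided binomial test per region given the library totals, with Benjamini-Hochberg adjustment, and by the mean squared binomial residual over regions. The latter was compared with 10000 random splits of the summed counts. Correlations, the SD of log2 ratios and the shared highest 10% of regions were compared with 200 such splits. The coefficient of variation beyond counting error is the square root of the covariance of the libraries divided by the product of their means. Fragments sequenced in both libraries, if there are any, would add counting error to it. Intervals of single counts are exact Poisson intervals and those of shares are exact (Clopper-Pearson) binomial intervals, two-sided at 95%, and the limit of 3 reads for a count of 0 is one-sided. Reads without molecular identifiers are not independent molecules, so the intervals of counts cover counting error only. Intervals of shares of regions treat the regions as independent draws.

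Stretches of region numbers were found by binary segmentation with a shortest stretch of 50 regions. Their means have block bootstrap intervals (2000 draws, blocks of 50 regions), since counts of adjacent regions are weakly correlated. The scripts were tested on simulated data with the real region totals. Segmentation placed 3 simulated breaks within 4 regions of their true positions. Those breaks were set near the observed positions and levels, with the regions otherwise in random order. Correlation of neighbouring regions and smaller breaks were thus absent, so the accuracy in the real order may be lower. The binomial test called 0%, 45% and 57% of 200 regions changed 2-, 4- and 8-fold, with 0, 3 and 2 unchanged regions called. Library 2 was raised in some changed regions and lowered in an equal number, so these shares average both directions.

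Before the data were examined, the sample grouping, the use of correlations and differences between libraries, a rule for named regions and the processing alternatives were fixed. The binomial test per region, the binomial residual and the segmentation were chosen after seeing the data. For the agreement of the libraries no p-value had been planned, since regions are not independent replicates. The p-values given for it are a departure from that plan. The rule named the 10 highest regions and a set number of regions with the largest difference between the libraries. It did not name the log2 ratio, which was the measure of difference used here. Regions carry numbers and no gene names, and the regions next in rank by log2 ratio were tied. The regions named for their difference were therefore limited to 1 in each direction, a departure from the rule. Gene lists for Treg, other immune and unrelated cells, and the share of regions in promoters, exons and introns, had also been planned. They were not run because positions of the regions were not analysed here, and region numbers were not matched to any annotation by their order. Alternatives restricted the regions to those above the median count, as planned, or, added after seeing the data, set a count minimum of 10, left out or capped the 10 highest regions, used single libraries, or changed the reference for the stretches.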

Results

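H3K4me1, the monomethylated form of lysine 4 on histone H3, is found at enhancers and on the flanks of active promoters. It was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in activated regulatory T (Treg) cells, the Foxp3-expressing CD4 T cells that restrain immune responses. The cells came from an adult male mouse aged 4 months of a Foxp3CreERT2 by Rosa26YFP strain, in which cells expressing Foxp3 can be marked by a fluorescent protein after induced recombination. The labels describe 1 group with 1 biological replicate, from which 2 technical libraries were made. Resting Treg cells, other histone marks and an input or control immunoprecipitation were not analysed here, so the data address how H3K4me1 reads were spread over a fixed set of regions and how closely the libraries repeated each other. Each library had a read count for the same 33643 regions, which carry a number and no position or gene name. No region could therefore be assigned to a gene, a promoter or an enhancer, and the values below refer to numbered regions of the mm10 assembly.

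Nearly every region held reads of the H3K4me1 libraries, which include background reads because no input control was used. The origin of the regions is not given, so they may have been chosen for having reads. Technical library 1 held 384814 reads over the regions and technical library 2 held 369421, so library 1 had 4.17% more reads in the regions. The median region had 10 reads in either library. The middle 50 percent of regions lay between 6 and 15 reads in both, and the 95th percentile was 25 reads in library 1 and 24 in library 2. In library 1, 214 regions (0.636%, exact 95% interval 0.554% to 0.727%) had no read, against 251 (0.746%, 0.657% to 0.844%) in library 2. Only 27 regions had none in both. A count of 0 allows a level of up to 3 reads, as a one-sided 95% limit. The intervals of these shares treat regions as independent draws with the same chance of having no read. The limit for a count of 0 covers counting error only.

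**Figure D1:**
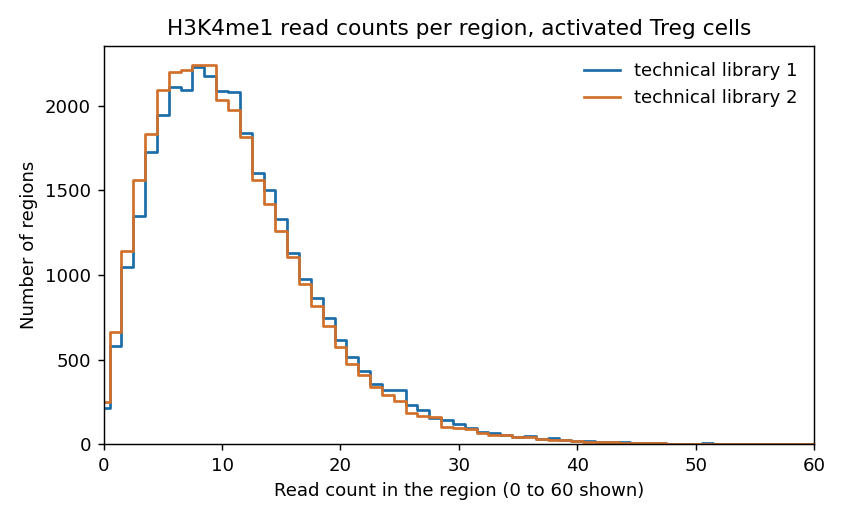
Number of regions (vertical axis) at each read count from 0 to 60 (horizontal axis) for technical library 1 (blue) and technical library 2 (orange) of the activated Treg sample. Both distributions have a median of 10 reads, and 17 regions exceeded 60 reads in at least 1 library and lie outside the plot.

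Region levels were unequal beyond counting error. With both libraries summed, the 754235 reads gave a mean of 22.4 and a median of 20 reads per region. The variance across regions was 10.9 times the mean, and 7.87 times without the 10 highest regions. Poisson counts from equal regions would give 1. The coefficient of variation of region levels, estimated from the covariance of the libraries, which leaves out counting error that is independent between them, was 66.6%, and 55.6% without the 10 highest regions. The highest 10% of regions (3364) held 23.1% of all reads, and the lower 50% held 27.6%. The widths of the regions were not analysed here, so a higher count can reflect a wider region as well as a denser mark. For a region at the summed median of 20 reads, the exact Poisson 95% interval was 12.2 to 30.9 reads. Those bounds lie at -38.9% and 54.4% relative to the count.

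A small set of regions stood far above the rest. Region 6635 had 474 reads in library 1 and 457 in library 2, a sum 46.6 times that of the median region. Region 18076 followed with 400 and 360 reads. Summed counts were 487 for region 4941, 440 for region 12073, 389 for region 8283, 386 for region 13152, 365 for region 1419, 345 for region 26163 and 286 for region 5856. The next, region 15676, had 179. These 10 regions together held 4568 reads, or 0.606% of the total. Library 1 contributed 52.3% of their reads and 51.0% of all reads, and a chi-square test over the 10 regions found no departure from the overall split (chi-square 5.56, p = 0.851). That test adds up the departures of single regions and has little power for a small shift common to all 10, which was not tested.

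Comparing the technical libraries asked how far a region's count repeats. No region passed the test for a difference. An exact two-sided binomial test per region, given the library totals, called 0 of 33616 regions with at least 1 read at a Benjamini-Hochberg adjusted p under 0.05. The lowest adjusted p was 1. At an unadjusted p under 0.05 there were 1151 regions, whereas splitting the summed counts at random gave 1231 ± 21.7 (SD over 20 simulated splits). On the scale of log2(count + 1), region 23948 had the largest excess in library 1, with 11 reads against 0, and region 25472 the largest in library 2, with 0 against 12. In libraries simulated from the real region totals, the test called 0% of 200 regions changed 2-fold and 45% of 200 regions changed 4-fold. Library 2 was raised in some of these regions and lowered in an equal number. Raised regions thus had more reads than the real ones and lowered regions fewer, and the 45% averages both directions. A 2-fold difference in a region of ordinary count was not detectable at this depth. The simulated changes were placed in regions drawn at random from those with at least 10 summed reads, and do not describe the highest regions.

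Across regions, which are not independent replicates, the counts of the libraries had a Pearson r of 0.84 and a Spearman rho of 0.75. Random splits of the summed counts gave 0.83 and 0.74 (SD 0.0014 and 0.0018 over 200 splits). Without the 10 highest regions the Pearson r was 0.78. Among 17338 regions with at least 20 summed reads, the log2 ratio between libraries had an SD of 0.51, and random splits gave 0.52. Of the highest 10% of regions in library 1, 58.8% were also in the highest 10% of library 2, and random splits gave 58.3%. The mean squared binomial residual over regions was 0.974, where 1 is pure counting noise. The libraries thus differed by less than the sampling noise. They were counted as 1 sample in what follows, with n = 1, and no spread between animals could be given.

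**Figure D2:**
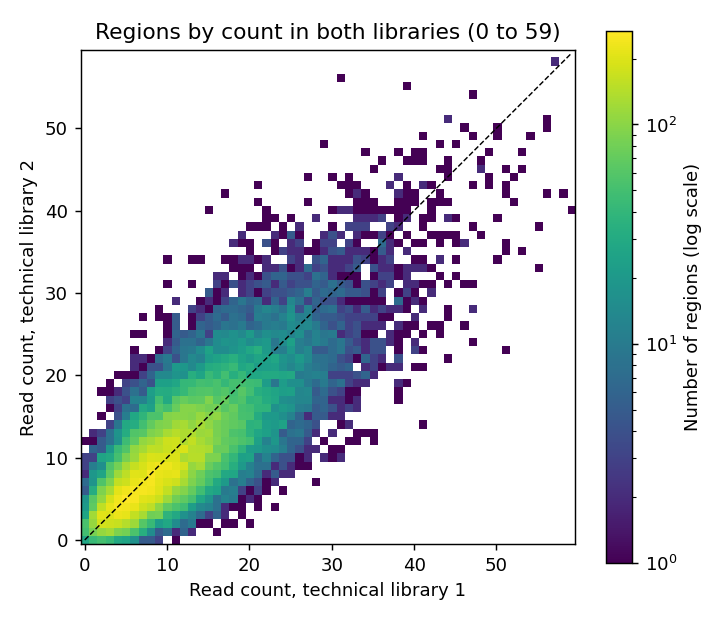
Number of regions (colour, log scale) at each pair of read counts in technical library 1 (horizontal axis) and technical library 2 (vertical axis), for counts of 0 to 59, with the line of equal counts dashed. Regions lie around the line, with a Pearson r of 0.84 across all regions and 51.0% of all reads in library 1.

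Counts changed in steps along the region numbers. Least-squares segmentation of log2(count + 1), chosen after seeing the data, placed its first 3 breaks after regions 20108, 20633 and 33517. Regions 1 to 20108 averaged 24.6 reads (95% block bootstrap interval 24.3 to 24.9), and the following 525 regions averaged 9.61 (9.11 to 10.1). Regions 20634 to 33517 averaged 19.7 reads (19.3 to 19.97), and the last 126 regions averaged 8.07 (7.15 to 9.01). Each long stretch thus ended in a short one at a lower level, with a ratio of 0.390 (0.370 to 0.411) in the first case and 0.411 (0.366 to 0.460) in the second. The second long stretch lay at 0.799 (0.782 to 0.815) of the first. Each technical library showed all 3 ratios on its own, at 0.393 and 0.388, 0.418 and 0.403, and 0.801 and 0.797. The gains of these breaks were 2009, 482 and 220 in units of the variance, against at most 15.9 in 100 shuffled orders. Smaller breaks with gains of 54.5, 44.5 and 23.2 followed within the second long stretch.

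**Figure D3:**
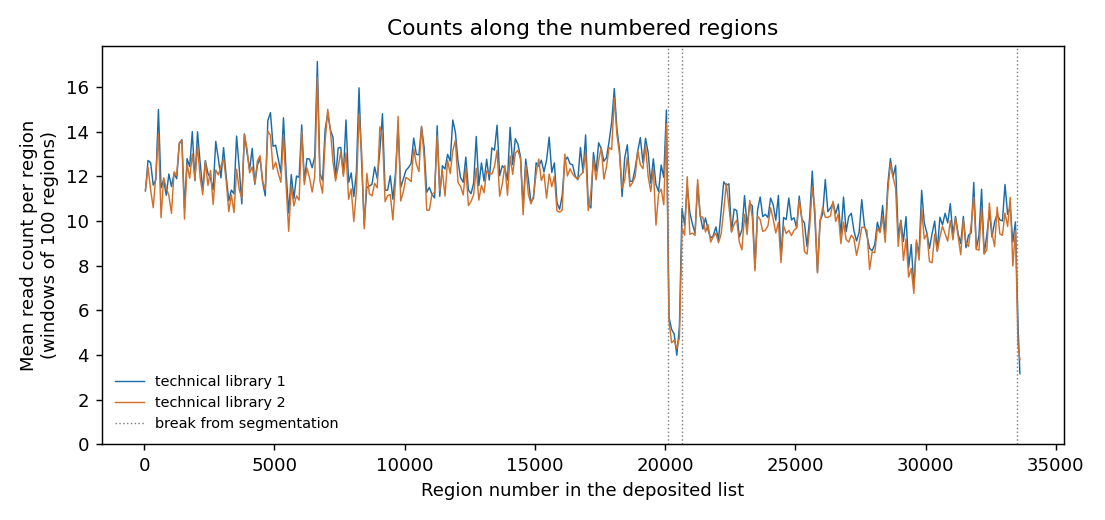
Mean read count per region in consecutive windows of 100 regions, the last one shorter (vertical axis) along the region number (horizontal axis), for technical library 1 (blue) and technical library 2 (orange), with the 3 breaks as dotted lines. Both libraries drop after region 20108, recover to a lower level after region 20633 and drop again after region 33517.

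Counts of neighbouring regions in the numbering were also weakly correlated. After the mean of each stretch was removed, log2 counts of adjacent regions had a Pearson r of 0.098 across 33642 pairs, and regions 10 apart had an r of 0.026. The smaller breaks within the second long stretch were left in and can contribute to both values. For either distance, no shuffled order was as high (one-sided permutation p = 0.0001, the smallest that 10000 orders can give). At a distance of 100 regions, r was -0.00034 (permutation p = 0.529).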

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

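The restriction to regions above the median count was planned for yield and agreement, before the residual and the test per region were chosen as measures of agreement. The other alternatives were chosen after seeing the data. With only regions above the median summed count, the mean count per region was 32.9, the Pearson r between libraries 0.787 and the Spearman rho 0.421. Without the 10 highest regions the Pearson r was 0.779. Single libraries put 23.8% to 23.9% of reads in the highest 10% of regions. The higher mean follows from the selection itself. Leaving out low or the highest regions narrows the range of counts in a correlation, and a single library has fewer reads per region. How far this accounts for the other shifts was not tested. The residual of the split was 0.971 to 0.974 under its alternatives, with a simulation p under 0.05 in each, and the count of regions that differ was 0 in each. The 3 ratios between stretches, all taken at the breaks placed on the summed counts, stayed below 1 with their whole intervals. The ratio of the long stretches was 0.773 from medians, below its reported interval. The alternatives for promoter distance, gene windows, gene lists in single libraries and enrichment curves were not run, since the tables hold neither positions nor curves. With 1 library left out, agreement has no value. Counting error limits what a single region shows, with an interval of 12.2 to 30.9 reads at a summed count of 20. No paired analysis was possible because there is only 1 group.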

Other observations

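The tests of the highest regions, of the stretches of region numbers and of the residual between libraries and its explanations were chosen after the results were seen. The 9 regions with 280 or more summed reads were spread over the numbering, with 8 in the first long stretch of regions and 1 in the second. Library 1 held between 50.9% and 54.8% of the reads of each. The lowest count of any of them in either library was 139 reads (exact Poisson 95% interval 117 to 164), against a median region of 10, so molecules amplified for only 1 of the 2 tables do not account for them. The labels call these separate technical libraries, but whether they are runs of a single amplified library was not settled, and amplification common to both stays open. Repeated sequence, wide regions and dense H3K4me1 also stay open and were not tested, and no biological explanation was tested.

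The drop of counts in regions 20109 to 20633 and again in the last 126 regions is not an effect of chance order, since the weakest of the 3 breaks had a gain of 220 and the highest gain in 100 shuffled orders was 15.9. Nor are the drops a matter of some regions nearly without reads. Of the first short stretch 5.33% and of the second 10.3% had 2 or fewer summed reads, where 60.95% and 58.9% would have to be empty. No input control was used, so regions that lack the mark but hold background reads are not covered by that comparison. A hypothesis is that the list joins 2 sets of regions, each ordered by chromosome, and that each ends with the X chromosome, which is present in 1 copy in cells of a male mouse. To examine a halved copy number as the whole difference, equally long windows of the preceding stretch were divided by 2. For the first short stretch, 0% of 19584 windows reached its mean of 9.61 (lowest 11.0). In the second case, 2.59% of 12759 windows reached the mean of the short stretch. The windows overlap, so far fewer of them are independent, and the widths of the regions and the background reads are not known. The first short stretch lay below every window divided by 2. For regions otherwise like those of the preceding stretch, this argues against a halved copy number as the whole difference there. For the second short stretch it cannot be excluded. A copy number effect joined by weaker or narrower regions may also apply to both, and positions of the regions would be needed to decide it.

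The libraries resembled each other more than independent sampling would give. The residual of 0.974 was lower than in random splits (simulation p = 0.000800, two-sided, over 10000 splits of the counts by a binomial model), a deficit of 2.62% (95% interval 1.15% to 4.09%). One candidate explanation is that a few percent of reads come from the same fragments, sequenced in both libraries, which would lower the residual evenly. Another is a ceiling of 1 read per position after duplicate removal, which would lower it more where counts are high if regions have similar widths. The widths are not known. The residual of regions at or below the median count exceeded that of the others by 0.0020 (95% interval -0.027 to 0.031). That interval includes both 0 and the 0.024 expected if the deficit grows with the count, so the explanations cannot be told apart at this depth. No biological explanation was tested.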
